A study of Mus musculus with 3 samples.

How the data were processed

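Whole mouse uterus at pregnancy day 7.5 was dissociated with trypsin and loaded on a droplet single-cell chip with 3' chemistry, per the labels' protocols. The series names 3 single-cell samples. 1 of them, whose labels give no genotype, was analysed, and the other 2 (Prl8a2-iCre with a Sun1-GFP reporter, and the reporter without Cre) are not analysed here. The values are UMI counts per gene and barcode, deposited by the authors as a sparse matrix made with Cell Ranger 4.0.0, per the file headers. The genome was mm10, per the submitters' processing notes. The annotation release and the settings by which the authors called cells are not given in the sources used here, and no deposited barcode had fewer than 500 UMIs. The matrix held 32287 features, including the added sequences sfGFP-Myc and iCre. 40 features that shared a gene symbol with another were summed with it, which left 32247 symbols. Gene coordinates are from GENCODE M21 on GRCm38, 1-based, and were used only for genes whose identifier matched the deposited one.

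Cells were kept with at least 500 detected genes and at most 20% of UMIs from mitochondrial genes. Of 2775 barcodes 2382 passed the first and 2064 the second filter, and 1825 passed both. Scrublet, as in scanpy 1.11.5, marked 13 of these (0.712%) as doublets at an expected rate of 5%, and they were removed, which left 1812 cells (65.3% of barcodes). The low rate means that undetected doublets may remain. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 with seed 0 gave 21 clusters. Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used. The list genes were left out of clustering, and none of them is a marker. Clusters were named from 179 markers in 22 sets fixed before the data were examined, by the set with the highest mean log2 CPM (pseudocount 5 CPM) over the median of the clusters. Stromal clusters were then divided into decidual and undifferentiated by the same score taken among themselves. A cluster stayed unnamed with fewer than 3 markers of its set in at least 10% of its cells. It also stayed unnamed if its median UMI count was under the library median divided by 3 with no marker of its set among its 10 leading genes, or if another class had more of its markers among them, and at least 2. The demand for at least 2, and the joining of monocyte, macrophage and dendritic clusters into 1 phagocyte class, were set after clusters and alternatives had been seen. Names may differ from the authors' own.

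22 gene lists with 543 genes were fixed before the data were examined, of which 542 genes were in the matrix. They cover the prolactin family, BMP and activin signalling, WNT signalling, steroid receptors and decidual regulators, angiogenic ligands, angiogenic receptors, S phase, G2 and mitosis, cyclins and endoreduplication, glycolysis and hypoxia, retinoid metabolism, matrix, chemokines, class I antigen presentation, cytokines, granzymes, cholesterol and steroid metabolism, the unfolded protein response, imprinted genes, early response and heat shock genes, Y-linked genes and Xist. Counts were summed over the cells of a class or cluster and divided by their total (CPM), with exact Poisson 95% intervals. Ratios of 2 sums have exact conditional binomial intervals and shares have Clopper-Pearson intervals. A gene was compared with at least 50 UMIs over both sides and counted as higher or lower at 2-fold or more with an interval that excludes 1. A list's median log2 ratio is given with its percentile among 10000 random lists of the same size matched on mean expression, as a description of this library. Where 1 side had 0 UMIs, "at least" folds use the limit of 3 counts over that side. Cells are not replicates, so no test between groups was made and no p-value is given.

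The text names the genes a fixed rule took: in each list and comparison the 2 members with the highest and the 2 with the lowest ratio that met the size rule. Always named where detected were Prl8a2, Prl3c1, Bmp2, Wnt4, Hand2, Pgr, Esr1, Foxo1, Vegfa, Angpt2, Flt1, Kdr, Ccnd3, Cdkn1a, Cdkn1c, Il15, Xist and 4 Y-linked genes. Where the rule took more than about 30 genes, mostly the most extreme of each direction is named. The choice among levels by class, and of H19, Igf2, Mest, Peg3, Hand1, Pou5f1, Gzma, Sct, Prl6a1 and the decidual markers, was made after the values were seen. Shares of cells with a UMI are over all cells of the group and not matched for depth, except where given as thinned. For thinned shares and for the cycling calls, cells were thinned to 2000 UMIs and shallower cells left out, unless another depth is given.

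On simulated counts for the decidual against undifferentiated comparison, with 7421 genes, the size rule took 100% of 56 genes changed 3-fold and of 59 genes changed 6-fold, 5.45% of 55 genes changed 1.5-fold and 0.303% of 7251 unchanged genes. The intervals held 96.0% of the true ratios. These counts were Poisson draws around 1 pooled profile, which the intervals assume. The shares therefore do not cover variation between cells or between clusters of a class. Of 1812 simulated cells 100% returned to the class they were drawn from. These cells were drawn from each cluster's mean, so real cells are harder to assign. Alternatives tried were other filters on cells, doublets kept, other resolutions, more variable genes, Pearson residuals, list genes allowed in clustering, another seed, equal weight per cell, another UMI minimum and other thinning depths and calls. Single clusters, nuclear-gene totals, a stricter cycling call and a stricter naming rule were added after seeing the data. So were the comparisons of NK-like clusters, of undifferentiated clusters and of endothelium, epithelium and mesothelium with all other cells.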

Results

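The series asks how the cells of the mouse uterus are composed in early pregnancy, and its single-cell part holds 3 samples of whole uterus taken at pregnancy day 7.5, when the stroma around the implanted conceptus turns into decidua. 1 library, whose genotype the labels do not give, was analysed. A sample with a Cre recombinase driven from the Prl8a2 locus and a Cre-dependent nuclear envelope reporter, and a sample with the reporter alone, are not analysed here. The library held 16848794 UMIs (unique molecular identifiers, each counting 1 captured transcript), with a median of 3225 UMIs per barcode. After filtering, 1812 cells remained with 14622717 UMIs, a median of 4509.5 UMIs and a median of 1866 detected genes per cell. There is 1 library per condition, so no difference below has a replicate check. Intervals are exact 95% intervals that cover counting error only and not the variation between animals.

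Which cell classes the dissociated uterus yielded was the first question. Stroma, immune cells and epithelium made up most of the library, and the cells divided into 21 clusters that fell into 10 named classes. Undifferentiated stroma-like cells were scored on 10 fixed markers, mostly collagen and other matrix genes. In both of their clusters Dpt, Fbln1 and Serpinf1 were higher than in both decidual clusters, while Col1a1, Col1a2 and Col6a3 were lower. This class was the most frequent, with 431 of 1812 cells (23.8%, 21.8 to 25.8). Epithelium-like cells followed with 373 cells (20.6%, 18.7 to 22.5), then NK cell and innate lymphoid-like cells with 310 (17.1%, 15.4 to 18.9) and mononuclear phagocyte-like cells with 268 (14.8%, 13.2 to 16.5). Decidual stroma-like cells, scored on 8 fixed markers of which Tdo2, Gja1 and Dio3 were higher than in undifferentiated stroma while Cdh11 and Htra1 were lower, numbered 134 (7.40%, 6.23 to 8.70), which was 23.7% (20.3 to 27.4) of all stromal cells. Smaller classes were mesothelium-like (88 cells, 4.86%), endothelium-like (67, 3.70%), T cell-like (45, 2.48%), pericyte-like (36, 1.99%) and B cell-like (24, 1.32%). Immune cells together made up 35.7% (33.5 to 38.0) of the library, and 47.9% (44.0 to 51.8) of them were NK-like. The phagocyte class joined a monocyte-like, a macrophage-like and a dendritic-like cluster of 167, 78 and 23 cells. These clusters were mixed in their markers. The macrophage-like cluster held more of the dendritic markers Ccr7 (482 CPM) and Cd209a (229) than the dendritic-like cluster (71.9 and 0), where most other dendritic markers were higher. The monocyte-like cluster held the neutrophil markers S100a8 (240 CPM) and S100a9 (272), but 0 of Ly6g. 1 cluster of 36 cells with a median of 1183 UMIs stayed unnamed. No cluster was named for smooth muscle, trophoblast or embryonic endoderm, although Myh11 and Acta2 of smooth muscle were among the leading genes of the pericyte-like cluster. The decidual-like share was 3.70% with at most 10% mitochondrial UMIs per cell and 10.9% with no filter on genes or mitochondrial share. The median mitochondrial share was 11.6% in decidual-like cells against 4.41% in undifferentiated cells. With no filter epithelium-like cells were the most frequent class, with 26.3% against 16.0% undifferentiated, so the shares and their order depend on these filters.

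**Figure D1:**
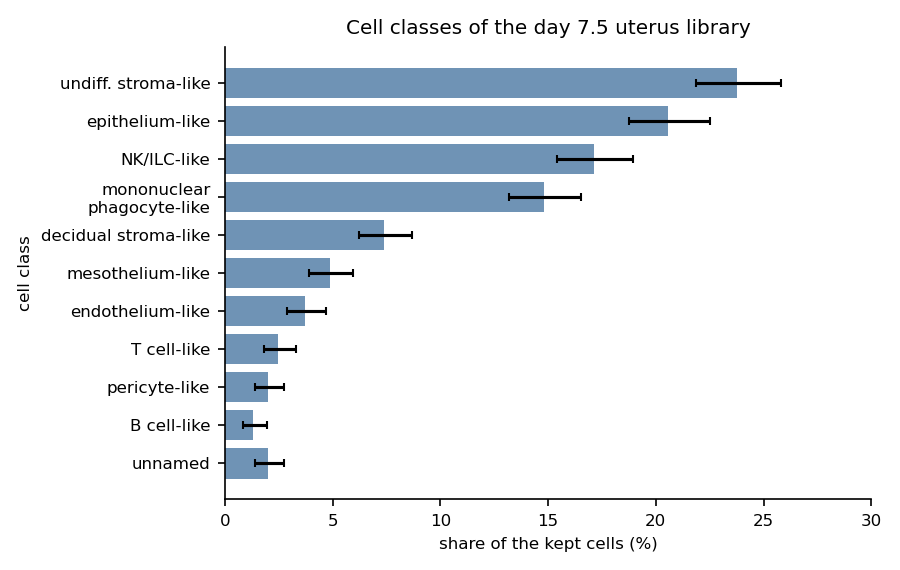
Share of the 1812 kept cells in each cell class (bars, in percent) with exact binomial 95% intervals (black lines) in the 1 library analysed. Undifferentiated stroma-like cells lead with 23.8%, and decidual stroma-like cells make up 7.40%.

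The decidual cells were then set against the undifferentiated stroma from which they arise. As a class, decidual-like cells held more transcript of the growth factor genes Bmp2 and Wnt4, of the glucose transporter gene Slc2a1, of the ribonucleotide reductase gene Rrm2 and of mitosis genes. They held far less of the BMP antagonist Nog, of the glucocorticoid-inactivating enzyme gene Hsd11b2 and of the immediate early genes. Bmp2 (chromosome 2, 133552159 to 133562885, GRCm38) stood at 298 CPM (counts scaled to the same total in each group) against 21.9, a ratio of 13.6 (9.61 to 19.8) that came from decidual cluster 1 (412 CPM), since cluster 17 with 57 of the 134 cells held 12.6 CPM, no more than undifferentiated stroma. Wnt4 (chromosome 4, 137277489 to 137299726) stood at 161 CPM against 5.64, a ratio of 28.5 (14.8 to 63.2). With cluster 1 alone that ratio was 38.7, and cluster 17 held far less Wnt4, as given below. Nog (chromosome 11, 89300638 to 89302332) was 23.7-fold lower (17.2 to 33.7), at 27.5 against 653 CPM. The sums covered 1380559 UMIs of 134 cells and 1596478 UMIs of 431 cells. Over all fixed lists, 283 genes had at least 50 UMIs, of which 68 lay at least 2-fold higher in decidual-like cells and 65 at least 2-fold lower. Both decidual clusters lay apart from both undifferentiated clusters for 40 of the higher and 62 of the lower genes. All genes together had a median log2 ratio of -0.31, which is the level that list medians are read against.

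The lists of G2 and mitosis genes and of glycolysis and hypoxia genes had the highest medians. Both lists stood higher in cluster 1 than in cluster 17. As a sum, G2 and mitosis genes reached 2618 CPM in cluster 1 but 859 CPM in cluster 17, below the 1248 CPM of undifferentiated stroma. Both decidual clusters still lay above both undifferentiated clusters for 4 of the 9 mitosis genes and 4 of the 8 glycolysis genes counted as higher below. In the list of G2 and mitosis genes, 9 of 21 measured members were at least 2-fold higher and 0 lower, with a median log2 ratio of 0.92 that lay at percentile 100 of random lists matched on expression. Anln, which encodes anillin of the cleavage furrow, was 18.1-fold higher (5.83 to 91.0). Of the S phase genes, 5 of 18 were higher and 0 lower (median 0.19, percentile 98.2), led by the ribonucleotide reductase gene Rrm2 at 715 against 17.5 CPM. Of the glycolysis and hypoxia genes, 8 of 19 were higher and 0 lower (median 0.83, percentile 100), and Slc2a1 reached 283 against 10.0 CPM. In the cyclin list 1 of 14 was higher and 4 were lower (median -0.42, percentile 32.4): Cdk6 was 2.99-fold higher (2.05 to 4.45) and Ccnd2, a D-type cyclin gene, lower at 2.17 against 73.9 CPM. Ccnd3, the cyclin gene linked to decidual polyploidy, had a ratio of 1.33 (0.987 to 1.79), Cdkn1a of 0.861 (0.527 to 1.39) and Cdkn1c of 1.31, all with intervals that include 1.

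Signalling and steroid lists were split in direction. Of the BMP and activin genes, 6 of 16 were at least 2-fold higher and 4 lower (median 0.18, percentile 94.5). Of the WNT genes, 7 of 19 were higher and 8 lower (median -0.32, percentile 35.9), and among the secreted WNT inhibitors Sfrp5 was at least 60.5-fold higher, with 157 UMIs against 0, while Sfrp2 was 6.05-fold lower (4.80 to 7.71). Steroid receptor and decidual regulator genes stood low as a list, with 3 of 27 higher, 7 lower and a median of -0.66 at percentile 0.915. The progesterone receptor gene Pgr (chromosome 9, 8899833 to 8968611) had 314 against 467 CPM, a ratio of 0.671 (0.595 to 0.757), the estrogen receptor gene Esr1 0.632 (0.562 to 0.709) and Foxo1 0.504 (0.345 to 0.725). Foxo1 stood lower in decidual cluster 1 than in cluster 17, as given below, so its class ratio does not describe each cluster. Hand2, a progesterone-responsive transcription factor gene of the stroma, had a ratio of 1.74 (1.54 to 1.98), but with cluster 17 alone 1.16 (0.939 to 1.42), which includes 1. Fkbp5, a target of steroid receptors, was 3.12-fold higher (2.48 to 3.95) and the Hedgehog receptor gene Ptch1 6.87-fold lower (4.30 to 11.6). Retinoid metabolism genes stood high (5 of 11 higher, 1 lower, median 0.79, percentile 99.9), with the retinoic acid-degrading enzyme gene Cyp26b1 at 84.8 against 11.3 CPM, carried by decidual cluster 17 (258 CPM, against 15.2 CPM in cluster 1), and Rarres2 4.27-fold lower (2.94 to 6.37). Of the cholesterol and steroid genes, 5 of 12 were higher and 4 lower (median 0.55, percentile 99.6). Idi1 of cholesterol synthesis was 7.25-fold higher (4.18 to 13.5) and Hsd11b2 was 21.4-fold lower, at 53.6 against 1148 CPM.

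Matrix, vascular and immune lists held members in both directions. Of the matrix genes, 10 of 35 were higher and 7 lower (median -0.37, percentile 27.6), with the laminin gene Lama5 19.8-fold higher (12.0 to 35.1) and the protease gene Adamts5 18.7-fold lower (6.13 to 93.2). Angiogenic ligands had 3 of 14 higher and 6 lower (median -0.33, percentile 44.9), and receptors 3 of 11 in each direction (median -0.49, percentile 20.5). Angpt4 stood at 75.3 against 1.25 CPM, a ratio of 60.1 with a lower bound of 16.2, and the netrin receptor gene Unc5b 55.9-fold higher (18.7 to 274), while Angptl2 was 21.8-fold lower (8.27 to 81.7) and Ramp3 18.4-fold lower (6.04 to 91.8). All decidual-like Angpt4 UMIs lay in cluster 1, with 0 in cluster 17, and Unc5b was also higher in cluster 1. Both decidual clusters lay above both undifferentiated clusters for 1 of the 3 higher ligands and 2 of the 3 higher receptors. Cxcl14 was 4.89-fold higher (4.54 to 5.27) and Cxcl12 6.02-fold lower (3.94 to 9.56), as 2 of the 3 chemokines measured. Among cytokines and immune modulators 2 of 11 were higher and 1 lower (median 0.28, percentile 96.0). The prostaglandin synthase gene Ptgs2 was 4.67-fold higher (2.96 to 7.64) and Tgfb3 2.62-fold lower (1.82 to 3.82). For 0 of these genes did both decidual clusters lie apart from both undifferentiated clusters, and Ptgs2 was higher in cluster 1 than in cluster 17. Il15 stood at 16.7 against 16.3 CPM. Class I antigen presentation genes were low, with 3 of 6 at least 2-fold lower and 0 higher (median -1.13, percentile 1.55), among them H2-D1 at 33.3 against 127 CPM. Of 18 unfolded protein response genes none differed by 2-fold (median 0.37, percentile 97.7), and of 9 imprinted genes 1 did, Sgce, at 4.35 against 49.5 CPM (list median -0.24, percentile 53.4). All 18 early response and heat shock genes were measured and 14 of them were at least 2-fold lower (median -1.47, percentile 0), with Egr1 6.65-fold lower (5.25 to 8.53). Gzmf, the 1 granzyme measured, was 3.58-fold lower (1.97 to 6.96) at levels of 10.1 and 36.3 CPM, against 3833 CPM in NK-like cells. Xist, the transcript of the inactive X chromosome, had a ratio of 0.738 (0.711 to 0.766). The prolactin family and the Y-linked genes had no member with 50 UMIs. These ratios describe 1 library, and cell groups of different mitochondrial share and depth (median 7344 against 3330 UMIs per cell).

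**Figure D2:**
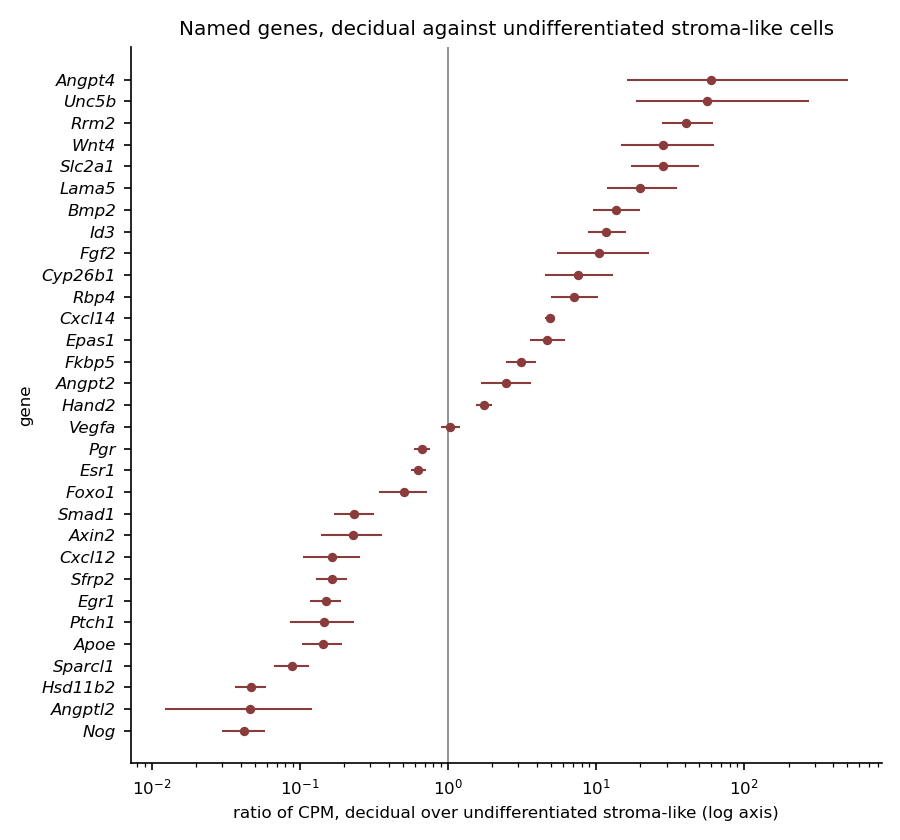
Ratio of summed CPM in decidual stroma-like over undifferentiated stroma-like cells (log axis) for 31 genes of the fixed lists, with exact 95% counting intervals (lines). The grey line marks a ratio of 1. Angpt4 lies highest at 60.1, with all its decidual-like UMIs in cluster 1, and Nog lowest at 0.0421, and the interval of Vegfa spans 1.

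Where Prl8a2 itself is transcribed was asked because it drives the Cre of a further sample. Prl8a2 (chromosome 13, 27345673 to 27354216, GRCm38), which encodes decidual prolactin-related protein, was close to undetected in this library, with 2 UMIs in all barcodes. 1 UMI lay in a decidual-like cell, which gives 0.724 CPM (0.0183 to 4.04) and 1 of 134 cells with a UMI (0.746%, 0.0189 to 4.09). The other lay in a mononuclear phagocyte-like cell (0.803 CPM, 0.0203 to 4.48), a class that should lack the transcript, with 0.373% of cells. The decidual-like level was therefore not above this background, at median depths of 7344 and 2570 UMIs. Thinned to 2000 UMIs, 0 of 117 decidual-like cells had a Prl8a2 UMI. In undifferentiated stroma-like cells 0 UMIs allowed up to 1.88 CPM. By comparison Tdo2 (chromosome 3), 1 of the markers that named the class, reached 2530 CPM in decidual-like cells. Of the 19 prolactin family genes listed, 15 had 0 UMIs in all barcodes, Prl3c1 among them. Members of this family share sequence, and how reads matching several of them were counted is not given in the sources used here.

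The decidual-like cells formed 2 clusters, which differed in growth factors, division and matrix. Cluster 1 (77 cells) held most transcript of Bmp2, Wnt4 and the angiogenic ligand genes Angpt2, Angpt4 and Hgf, together with higher cell division, glycolysis and protein folding genes. Cluster 17 (57 cells) held most Cyp26b1 and Rbp4 of retinoid metabolism, the collagen cross-linking enzyme gene Lox and the WNT inhibitor gene Sfrp4. Bmp2 stood at 412 CPM in cluster 1 and 12.6 in cluster 17, a ratio of 32.6 (13.9 to 101), and Wnt4 at 218 against 17.7, a ratio of 12.3 (5.89 to 31.1). Angpt2 stood at 87.3 against 2.53 CPM, and its ratio of 34.6 (6.04 to 1380) rests on 1 UMI in cluster 17. Hgf was at least 15.8-fold, Angpt4 at least 13.9-fold, Dkk2 at least 13.3-fold and Wnt6 at least 8.98-fold higher in cluster 1, each with 0 UMIs in cluster 17. The guidance and VEGF co-receptor gene Nrp1 was 18.2-fold higher (6.11 to 89.5) and Ptgs2 12.6-fold higher (4.18 to 62.2). In cluster 17, Cyp26b1 stood at 258 against 15.2 CPM, so that cluster 1 was 16.9-fold lower (9.79 to 31.3), and Rbp4 was 7.11-fold, Lox 6.22-fold, Hsd11b2 7.20-fold, Foxo1 4.81-fold and Sfrp4 4.16-fold lower in cluster 1. Of 199 list genes measured, 68 were at least 2-fold higher and 24 lower in cluster 1. G2 and mitosis genes (12 of 19 higher, median log2 ratio 1.51, percentile 100), glycolysis genes (10 of 15 higher, 1.36, percentile 100) and unfolded protein response genes (9 of 15 higher, 1.05, percentile 99.1) stood high, with 0 lower in each. Retinoid genes (2 of 7 higher and 3 lower, -0.91, percentile 0.05) and matrix genes (2 of 28 higher and 7 lower, -0.39, percentile 0.02) stood low. Pgr (0.907, 0.737 to 1.12), Esr1 (1.04, 0.847 to 1.29), Cdkn1a (0.517, 0.243 to 1.12) and Ccnd3 (0.816, 0.530 to 1.28) had intervals that include 1, Hand2 a ratio of 1.71 (1.40 to 2.10) and Vegfa of 0.610 (0.490 to 0.761). Cluster 17 had a higher mitochondrial share (median 13.5% against 9.83%) and fewer UMIs per cell (median 5700 against 9510).

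More angiogenic receptor genes had their highest level in the endothelium than in any other class, while the ligands were spread over several classes. The 1 endothelium-like cluster also held the lymphatic markers Ccl21a (307 CPM), Mmrn1 (299), Lyve1 (208) and Prox1 (98.4), though Pdpn was higher in other clusters. Blood and lymphatic endothelium were not separated here. Flt1 and Kdr, the main VEGF receptors, stood at 1038 CPM (953 to 1130) and 990 CPM (906 to 1080) in endothelium-like cells and at no more than 14.5 CPM in every other named class. Of 24 receptor genes measured over all classes, 14 were highest in endothelium-like cells, and in a comparison with all other cells, added after the data were seen, 18 were at least 2-fold higher and 4 lower there (median log2 ratio 4.09, percentile 100). Of the 24 ligand genes 7 were higher and 5 lower there in the same comparison (median -0.51, percentile 2.37). Vegfa (chromosome 17) was spread over several classes, with 254 CPM (228 to 282) in decidual-like, 244 (220 to 269) in undifferentiated stroma-like, 226 (213 to 239) in epithelium-like and 148 (136 to 161) in NK-like cells, against 21.2 (10.6 to 38.0) in endothelium-like cells. Decidual and undifferentiated stroma did not differ in Vegfa beyond counting error (ratio 1.04, 0.898 to 1.21). Angpt2, which encodes a ligand of the Tie2 receptor, stood at 78.2 CPM (47.8 to 121) in pericyte-like and 63.0 CPM (50.5 to 77.7) in decidual-like cells, 2.45-fold (1.67 to 3.65) above undifferentiated stroma. That excess also came from cluster 1 (87.3 CPM), since cluster 17 held 1 UMI (2.53 CPM), below the 25.7 CPM of undifferentiated stroma. With at most 10% mitochondrial UMIs the class ratio was 1.12. Angpt4 was highest in decidual-like cells (75.3 CPM, 61.6 to 91.3), Pgf in pericyte-like (145, 102 to 199), Pdgfb in endothelium-like (299, 254 to 350), with the receptor gene Pdgfrb at 1213 CPM in pericyte-like cells, Fgf1 in mesothelium-like (460) and Adm in epithelium-like cells (151, 141 to 162). The Angpt4 UMIs of decidual-like cells all lay in cluster 1. Of 24 ligand genes 6 were highest in decidual-like, 5 in endothelium-like and 5 in pericyte-like cells. Classes of few cells, such as the 36 pericyte-like cells, set wide intervals here.

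**Figure D3:**
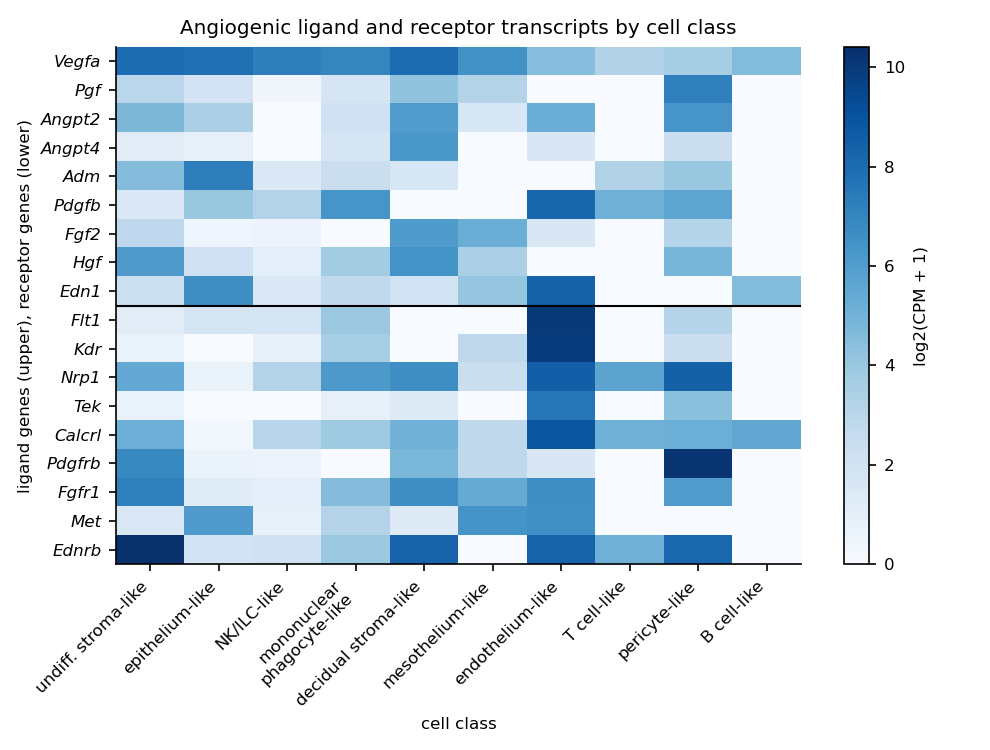
Transcript level, as log2(CPM + 1), of 9 angiogenic ligand genes and 9 receptor genes in the 10 named cell classes of the 1 library. Flt1 and Kdr are darkest in endothelium-like cells (1038 and 990 CPM), Pdgfrb in pericyte-like cells, and Vegfa is spread over stroma, epithelium and NK-like cells.

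Immune classes differed in the ligands they held. NK-like cells were marked by granzymes and osteopontin (Spp1), and mononuclear phagocyte-like cells by chemokines and interleukin 1 beta. All 7 granzyme genes measured were highest in NK-like cells, with Gzma at 2106 CPM (2060 to 2152) there against 6.52 in decidual-like cells. Of 19 chemokine genes, 11 were highest in phagocyte-like cells, including Ccl4 at 2978 CPM (2882 to 3075). Among the exceptions were Xcl1 in NK-like cells (288 CPM, 271 to 306), Cxcl14 in decidual-like cells (2688 CPM, 2602 to 2776) and Cxcl12 in endothelium-like cells (575 CPM, 512 to 644). Others were highest in epithelium-like (2 genes), T cell-like, mesothelium-like and undifferentiated stroma-like cells (1 each). Il1b reached 1925 CPM (1849 to 2004) in phagocyte-like cells, and Il15, a cytokine that NK cells need, was low in each class, with 26.5 CPM (18.2 to 37.2) in phagocyte-like, 16.7 in decidual-like and 16.3 in undifferentiated stroma-like cells. Of 28 cytokine and immune modulator genes 7 were highest in phagocyte-like and 5 in NK-like cells. Of 16 class I genes 5 were highest in phagocyte-like, 4 in B cell-like and 0 in decidual-like cells. None was highest in undifferentiated stroma-like, epithelium-like, endothelium-like or pericyte-like cells either.

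Within the NK-like class, cluster 6 (122 cells) and cluster 2 (153 cells) held different effector genes, a comparison added after the clusters were seen. Cluster 6 had all 7 granzymes at least 2-fold higher (median log2 ratio 6.52, percentile 100), and cluster 2 had all 5 chemokines measured at least 2-fold higher (median -4.70, percentile 0). Gzmf stood at 5803 against 41.3 CPM, a ratio of 141 (96.6 to 213), Gzmg was at least 204-fold higher with 0 UMIs in cluster 2, and Spp1 was 20.4-fold higher, at 3766 against 185 CPM. In cluster 6 Ccl5 was 124-fold lower (68.9 to 251), the interferon gamma gene Ifng 16.3-fold lower (10.8 to 25.4), at 13.7 against 223 CPM, and Vegfa 7.18-fold lower (5.94 to 8.72). S phase genes (17 of 31 higher, 0 lower, percentile 100), G2 and mitosis genes (12 of 27 higher, 0 lower, percentile 99.9) and unfolded protein response genes (10 of 19 higher, 3 lower, percentile 100) stood high in cluster 6. Early response genes stood low (14 of 17 lower, 0 higher, percentile 0), with Dusp1 17.7-fold lower (13.5 to 23.4). Cluster 15, with 35 cells, resembled cluster 6 in granzymes (Gzmf 2440 CPM) and was led by histone genes and the mitotic kinesin gene Kif11. Cluster 6 cells were deeper (median 14519.5 against 4129 UMIs).

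**Figure D4:**
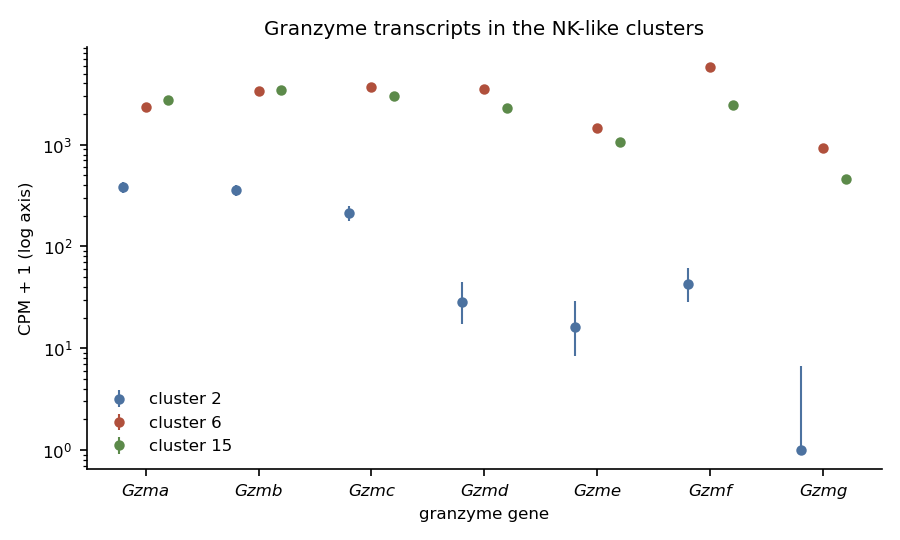
Transcript level of 7 granzyme genes (CPM + 1, log axis) in the 3 NK-like clusters of the 1 library, with exact 95% counting intervals (lines, often smaller than the points). Gzmf stands at 5803 CPM in cluster 6, 2440 CPM in cluster 15 and 41.3 CPM in cluster 2.

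Cell division transcripts were unevenly spread over the classes. NK-like cells held the most mitotic transcript of the named classes as a sum. Their cluster 15 (35 cells) reached 10326 CPM, while their clusters 6 (3082 CPM) and 2 (2007 CPM) lay below endothelium-like cells. Decidual-like cells held more than undifferentiated stroma in the sum over the class. That excess came from cluster 1 (2618 CPM) and not from cluster 17 (859 CPM). G2 and mitosis genes summed to 5017 CPM (4946 to 5088) in NK-like, 3496 (3336 to 3660) in endothelium-like, 2114 (2038 to 2192) in decidual-like and 1248 (1194 to 1304) in undifferentiated stroma-like cells. Phagocyte-like (3064 CPM), T cell-like (2535), pericyte-like (2499) and B cell-like cells (2250) lay between endothelium-like and decidual-like cells. S phase genes summed to 3253 CPM in NK-like, 2332 in endothelium-like, 2119 in decidual-like and 792 in undifferentiated stroma-like cells. Of the decidual sum, Rrm2, Rrm1 and Usp1 held 715, 363 and 263 CPM, against 17.5, 37.0 and 123 CPM in undifferentiated stroma, so these 3 genes carried most of the difference. The planned call of a cycling cell, at least 2 distinct G2 and mitosis genes after thinning to 2000 UMIs, set NK-like cells above stroma and epithelium but did not separate decidual-like from undifferentiated or epithelium-like cells with the filters used. With at most 10% mitochondrial UMIs decidual-like cells lay lower, with 39.5% (24.0 to 56.6) against 68.8% of undifferentiated cells (63.2 to 73.9). The planned call took 61.5% of decidual-like cells (52.1 to 70.4), 63.6% of undifferentiated stroma-like cells (58.1 to 68.8), 63.6% of epithelium-like (58.1 to 68.7) and 87.6% of NK-like cells (83.0 to 91.3), and also 92.3% of T cell-like cells. Before thinning these shares were 91.8%, 83.5%, 89.0% and 96.5%, and thinning left out 17, 107, 41 and 44 cells. A stricter call of at least 8 genes, chosen after the data were seen, took 9.40% of decidual-like (4.79 to 16.2), 0.309% of undifferentiated stroma-like (0.00781 to 1.71), 5.12% of epithelium-like and 15.8% of NK-like cells. By this call 16.1% (8.02 to 27.7) of cluster 1 cells and 1.82% (0.0460 to 9.72) of cluster 17 cells were taken in the decidua, and 82.9% (66.4 to 93.4) of NK-like cluster 15, against 0 of 117 cells (0 to 3.10%) of NK-like cluster 2. No background share of mitotic genes was measured, and no share is read as a rate of division.

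Cells of the conceptus were looked for through Y-linked genes, which the mother lacks, and through markers of trophoblast, endoderm and epiblast. No cell was identified as one. 5 of 1812 cells (5 UMIs) held a Y-linked transcript, 2 UMIs of Ddx3y and 3 of Kdm5d, while Eif2s3y and Uty had 0 UMIs, and no cell held 2 Y-linked UMIs. 3 of these 5 cells also held H19, an imprinted transcript of growing tissue, and lay in the unnamed cluster. Xist was detected in 92.8% of the kept cells. The trophoblast giant cell hormone gene Prl3d1 had 0 UMIs in all barcodes. Sct, which was fixed as a trophoblast marker, was among the leading genes of decidual-like cluster 1, in 28.6% of its cells. T, fixed with the epiblast markers, was detected in endothelium-like cells alone (17.4 CPM). Pou5f1, another of that set, stood at 9.65 CPM there and 9.30 CPM in undifferentiated cluster 4. H19 had 137 UMIs in 28 kept cells. In the unnamed cluster, 8 cells chosen for holding H19 also held 3 Y-linked UMIs (2 of Ddx3y, 1 of Kdm5d), 2 of the epiblast marker Pou5f1, 7 of Igf2, 7 of Peg3 and all 6 Hand1 UMIs of the library, a trophoblast and mesoderm marker. Its other 28 cells held 0 UMIs of each of these and 72 of Gzma, and Mest had 9 UMIs against 1. That split was made after the values were seen. The 8 cells had a median of 1396.5 UMIs per cell and formed no cluster of their own, so whether they came from the conceptus stays open. Y-linked genes mark male cells alone, so female conceptus cells were not countable this way.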

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

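The tests by depth and on the removed barcodes, the count of prolactin members and the early response median were chosen after the result was seen. The tests on Myc reads and on UMI counts within the decidual class were set before it. No biological explanation was tested, since 1 library was analysed.

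A signal appeared in a feature that no comparison uses. The reporter sequence sfGFP-Myc had 25 UMIs in 16 barcodes of the library, above the limit that a count of 0 allows, although its labels give no genotype, and no genotype is inferred from it. Of these UMIs 48% lay in 3 barcodes with at least 2 each, while 10000 random draws in proportion to depth gave at most 16% at their upper bound, which argues against free RNA spread evenly by depth. The 13 kept cells were 5 undifferentiated stroma-like, 3 endothelium-like, 3 epithelium-like and 2 NK-like. Reads of the mouse Myc gene counted as the tag may contribute: the distance between the class distribution of these cells and that of 836 Myc UMIs was 0.425, under the upper bound of 0.443, but with 13 cells this cannot be told apart. iCre had 1 UMI.

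Prl8a2 was nearly absent at 2 UMIs, although 134 decidual-like cells were kept. Removal of its cells by the filters is argued against, since the 963 removed barcodes held 0 Prl8a2 UMIs (a limit of 1.35 CPM) while they held 863 UMIs of the naming marker Tdo2. Loss of reads shared between prolactin paralogs stays open: of 19 family members 1, Prl6a1, had more than 3 UMIs, and without the reads no value decides. A low level of Prl8a2 in the decidual cells that this dissociation released is a further explanation that was not tested.

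Decidual-like cells had a median mitochondrial share of 11.6% against 4.41% in undifferentiated stroma-like cells. Loss of cytoplasmic RNA from damaged cells may contribute: cells above the class median had 0.554 times the non-mitochondrial UMIs of the others (median 5392 against 9725), but the resampling interval of 0.418 to 0.741 reaches past the bound set in advance, and a lower count also raises the share by construction. Early response and heat shock genes had a median log2 ratio of -1.47, below matched random lists, so they were not raised over undifferentiated stroma-like cells. A ratio cannot tell low levels in 1 class from raised levels in the other, and the value was known beforehand. Stress during dissociation therefore stays open. A difference in mitochondrial content between the classes stays open and was not tested.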

How the results depend on the processing

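Among the alternatives, single-cluster comparisons, nuclear-gene totals, the call of at least 8 genes and the stricter naming rule were chosen only after the result was seen. Each library stands alone, so leaving out replicates was not possible. No paired analysis was possible because 1 library was analysed. Of 196 values of the main results under an alternative, 162 stayed within their counting interval (counts within 1.5 times) and 34 moved. Of 163 values of single genes, 137 stayed and 26 moved. None of the ratios compared changed direction, but Bmp2, Wnt4, Angpt4 and Angpt2 had fewer than 50 UMIs with cluster 17 alone, and Angpt4 also with at most 10% mitochondrial UMIs, and were not compared there. As given above, cluster 17 held no more Bmp2 and less Angpt2 than undifferentiated stroma, so the higher class levels of these genes do not describe that cluster. The Hand2 ratio with cluster 17 alone was 1.16 (0.939 to 1.42), which includes 1. Among the settings compared, which leave out cluster 17 alone, the Angpt2 ratio ranged from 1.12 with at most 10% mitochondrial UMIs to 3.40. Bmp2 ranged from 8.47 to 20.1 and Wnt4 from 24.4 to 41.3 in the same way. From cluster 1 alone to cluster 17 alone, Nog ranged from 0.0155 to 0.108 and Hsd11b2 from 0.0168 to 0.121. With at least 200 UMIs, 34 list genes were higher and 38 lower in decidual-like cells, since fewer genes were measured, and with cluster 17 alone as the decidual side 25 were higher and 71 lower. At most 10% mitochondrial UMIs gave 56 higher and 82 lower. With at least 1000 genes per cell, the NK-like share was 19.1%, the phagocyte-like 10.5% and the decidual-like 9.11%. The filter at 10% mitochondrial UMIs gave 28.0% undifferentiated, 16.1% epithelium-like, 3.70% decidual-like and 5.97% mesothelium-like cells, and 39.5% cycling decidual-like cells. No filter gave 16.0% undifferentiated, 26.3% epithelium-like, 14.1% NK-like, 10.9% decidual-like, 3.19% mesothelium-like and 2.50% endothelium-like cells, and 68.9% cycling undifferentiated cells. The NK-like share was 19.1% at resolution 0.5, 14.0% at resolution 2 and 15.3% with more variable genes. Shares called cycling in decidual, undifferentiated, epithelium and NK-like cells were 38.8%, 32.6%, 31.2% and 66.4% when thinned to 1000 UMIs, 35.9%, 34.3%, 34.9% and 72.2% with at least 3 genes, and 9.40%, 0.309%, 5.12% and 15.8% with at least 8, as stricter calls take fewer cells. With at least 2 Y-linked UMIs, 0 cells were called. The stricter naming rule left the main shares as they were, but under it 7 of 10 alternatives had an NK-like share of 6.23% to 10.7%, 3 a phagocyte-like share of 4.19% to 4.42% and 1 fewer undifferentiated cells, because clusters went unnamed. Except where given, the cause was not tested. Depth limits the small classes most: 0 UMIs allow up to 67.5 CPM in B cell-like and 1.88 CPM in undifferentiated stroma-like cells.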

Other observations

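The comparisons of mesothelium-like and epithelium-like cells with all other cells and of the undifferentiated clusters, and all choices of genes outside the naming rule below, were made after the data were seen. Mesothelium-like cells, the lining of the outer uterine wall, held WNT activators and the growth factor gene Fgf1. Of 27 WNT genes, 13 were at least 2-fold higher and 7 lower there than in all other cells (median log2 ratio 1.09, percentile 100). Rspo1, a secreted WNT amplifier, stood at 296 CPM against 0.991, a ratio of 299 (173 to 561), Rspo3 was 22.1-fold higher (15.7 to 30.9), and Wnt4 was 9.36-fold higher (7.41 to 11.7) at 209 CPM, beside 218 CPM in decidual-like cluster 1 and 17.7 CPM in cluster 17. Fgf1 stood at 460 against 0.920 CPM and the retinoid-responsive chemoattractant gene Rarres2 98.3-fold (84.8 to 114). Mitotic genes stood low against the pool of all other cells, with 37 of 51 lower and 2 higher (median -2.46, percentile 0). Their sum of 1615 CPM lay above the 1248 CPM of undifferentiated stroma-like and close to the 1668 CPM of epithelium-like cells. The planned cycling call took 78.8% (68.2 to 87.1) of mesothelium-like cells, and the call of at least 8 genes 1.25%.

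Epithelium-like cells held the retinoic acid-degrading enzyme gene Cyp26a1 (chromosome 19, 37697798 to 37701536, GRCm38) at 266 CPM against 3.05, a ratio of 87.5 (60.6 to 131), where decidual-like cluster 17 held Cyp26b1 (258 CPM). The EGF family ligand gene Hbegf was 35.1-fold higher (30.1 to 41.3), the steroid 5-alpha-reductase gene Srd5a1 37.8-fold (29.0 to 50.1), Cxcl5 49.7-fold (24.8 to 117) and the macrophage growth factor gene Csf1 10.6-fold (9.04 to 12.6). Early response and heat shock genes stood high (12 of 18 higher, 0 lower, median 1.40, percentile 100) and matrix genes low (27 of 38 lower, 4 higher, median -3.49, percentile 0). Prl6a1 was the 1 prolactin family member above 3 UMIs: 42 of its 43 UMIs in kept cells lay in epithelium-like cells (8.23 CPM, 5.93 to 11.1), in 31 of 373 cells (8.31%), against 0 UMIs in decidual-like cells.

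Undifferentiated stroma-like clusters 5 and 4 differed less than the decidual clusters: of 213 list genes 23 were at least 2-fold higher in cluster 5 and 11 lower. Cluster 4 had fewer UMIs per cell (median 1960 against 4761.5) and a higher mitochondrial share (median 7.50% against 3.25%). Hsd11b2 stood at 1373 against 539 CPM, Id3 was 14.9-fold lower (6.94 to 36.7) and matrix genes stood high (6 of 27 higher, 1 lower, median 0.39, percentile 99.8).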
